A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

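The study hybridised RNA from 2 strains of the fission yeast Schizosaccharomyces pombe to Affymetrix yeast arrays, which carry probe sets of S. pombe and of the budding yeast Saccharomyces cerevisiae. The strains are called opi10+ and opi10- after the state of the opi10 gene. Each was sampled in minimal medium at 30C, after 1 h at 43C, and after 1 h and 3 h back at 30C. There were 8 arrays, 1 for each strain and condition. Per the labels, RNA was extracted with phenol and chloroform and amplified into biotinylated cRNA with a kit that primes at the 3' end of transcripts.

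The values used were intensity values on a linear scale, deposited by the authors as a table of 10928 probe sets. The method that summarised probes into probe sets, and any scaling the authors applied between arrays, are not given in the sources used here. The brightest probe set of each array lay between 12359 and 15296. No saturation calls were used here, so changes of very bright genes may be understated.

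Gene names came from the platform annotation supplied with the values, updated through Entrez identifiers to the symbols of the ASM294v3 assembly's gene table. Of the probe sets, 2914 had 1 S. pombe gene, 2601 had 1 S. cerevisiae gene, 20 had several genes, 3 had a name that could not be placed in either species, 213 were array controls, and 5177 had no gene in the annotation and are unnamed here. The 2914 probe sets stood for 2896 S. pombe genes, 113 of which had a newer symbol than the annotation. The array files name no genome build, so no coordinates are given.

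Values were transformed as log2(value + 16). The plan, fixed before the data were examined, was to keep the deposited scale unless array medians over S. pombe probe sets differed by more than 0.5 log2. They did, with medians from 8.99 to 10.1, so quantile normalization over the S. pombe probe sets was the main setting, and the deposited scale became an alternative. Fold changes are on the log2(value + 16) scale and understate changes of dim genes. Probe sets of S. cerevisiae served as a measure of background. A gene was tested when its mean over the 8 arrays lay above the 75th percentile of the S. cerevisiae probe sets, a signal of 5.72, and the brightest probe set stood for a gene with several. This left 2892 genes. Their median signal was 893.2, against 2.46 for S. cerevisiae probe sets.

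Heat shock and recovery were tested with limma (version 3.58.1, in R 4.3.3), by lmFit and eBayes, in an additive model with a term for strain and a term for condition over all 8 arrays, which leaves 3 residual degrees of freedom. Each condition then has 2 arrays, 1 per strain, and the residual measures how far the strains' responses differ. The strain term compares 4 arrays with 4. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The labels do not say whether the arrays of a strain came from 1 culture or several, so p-values measure the spread between these arrays only. Differences between the strains within 1 condition, and differences between the strains' responses, compare 1 array with 1 array. They have no replicate check and no test, and are given as values and as counts of genes beyond 2-fold.

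There were 26 gene lists, fixed before the data were examined, of which 25 had at least 3 measured members. For each list the number of called genes, the same number adjusted over the list alone, and the median change are given. Each median was placed among the medians of 10000 random lists matched on expression decile, as a description of these arrays. Some listed names turned out to belong to another gene on the array. Those found were ssp1 (chaperones and HSP70 family), mak1, mak2 and mak3 (ribosome biogenesis), lsd1 (sterol and fatty acid synthesis) and cds1 (phospholipid synthesis). The lists were kept as fixed, and recounted without these genes. Other such names may remain in the lists and in the recounts. Another 5 lists were written after some strain differences had been seen. Which lists the text describes was chosen after their medians were seen. Of the 25 lists, 7 lay above the 97.5th percentile of the random lists and 4 below the 2.5th at 43C, 4 and 7 at 1 h and 6 and 5 at 3 h of recovery. For the strain differences these counts were 5 and 7 before heat, 2 and 7 at 43C, 3 and 5 at 1 h and 9 and 5 at 3 h.

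Genes named in the text followed a rule fixed before the data were examined. It took the 8 largest called rises and falls of each contrast that went the same way in both strains, all HSP70 family members, the 4 largest changes of each described list, and the 4 genes highest and lowest in each comparison without a test. Genes named outside the rule are said to be.

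The alternatives were the deposited scale, centring on the median of genes other than ribosomal protein genes, pseudocounts of 1 and 64, no filter, a filter at the 95th percentile, all probe sets of a gene, leaving out each array, an intensity trend with robust moderation, leaving out a term of the model, and comparing the 43C arrays with all arrays at 30C. Centring on the spike-in probe sets, testing unnamed probe sets above the stricter filter leaving out the misplaced list members, and comparing list medians between scales relative to all genes in place of plain medians were added after seeing the data. The median standard error of a condition effect was 0.101 log2 and that of the strain effect 0.0717.

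The model was tested on simulated data drawn around the fitted values of the 2892 genes with their moderated variances, 200 genes being changed in each contrast. For heat shock, 98 of 100 genes changed by 1 log2 and 100 of 100 changed by 2 log2 were recovered, with 12 false calls. For 1 h of recovery 99 and 100 were recovered with 11 false calls, for 3 h 99 and 100 with 5, and for the strain term 100 and 100 with 8. The simulated noise was independent between genes, strain and condition effects added up, and all other genes had no change in the contrast. Strain-specific responses shared by many genes were thus not covered, and these counts do not measure the error of the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.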

Results

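The arrays measured transcript levels in 2 fission yeast strains, opi10+ and opi10-, before heat shock, after 1 h at 43C, and after 1 h and 3 h of recovery at 30C, with 1 array for each strain and condition. The gene opi10 is the fission yeast member of the Hikeshi family, whose human member carries HSP70 chaperones into the nucleus during heat stress. The design asks which transcripts heat shock changes, how far they return during recovery, and whether this depends on opi10. The median signal over S. pombe probe sets was 1004 and 922.4 before heat, 492.5 and 516.5 at 43C, 988.9 and 1024 at 1 h of recovery, and 1096 and 1041 at 3 h, in opi10+ and opi10- respectively.

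No probe set was paired with opi10 in the annotation used here, so its level could not be read by name in either strain. Among unnamed probe sets, 1772771_at, chosen after its values were seen, had a signal of 525, 1150, 448 and 818 in opi10+ before heat, at 43C and at 1 h and 3 h of recovery. It had 1.31, 1.16, 0.535 and 1.48 in opi10-, near the S. cerevisiae background of 2.46. Its gene is not given in the sources used here, so it does not check the labels.

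Condition separated the arrays more than strain did. All 8 arrays correlated best, across genes, with the array of the other strain at the same condition, with Pearson r from 0.989 to 0.994 for such pairs and 0.818 to 0.967 for others. Genes are not independent replicates in these values. The first principal component held 63.3% of the variance and the second 17.6%. The deposited values moved by a median of -0.915 log2 at 43C over all tested genes and of 0.105 at 3 h of recovery, while quantile normalization left medians of -0.07 and -0.03. Changes of named genes and lists below are after quantile normalization, unless the deposited scale is named, and so are relative to the other genes. Levels of the 27 spike-in probe sets moved by 0.08 log2 in opi10+ and -0.07 in opi10- from before heat to 43C.

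**Figure D1:**
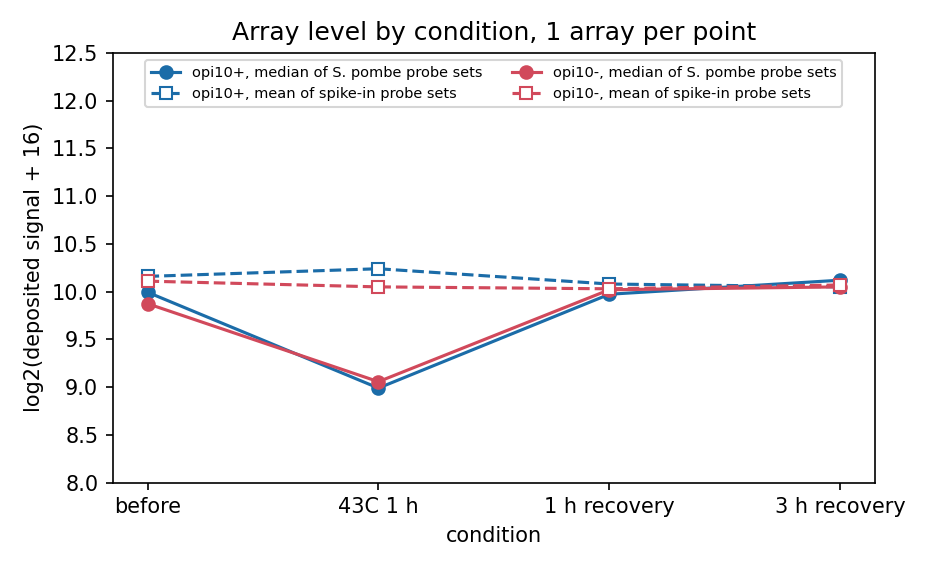
Median log2(signal + 16) of S. pombe probe sets (filled points) and mean of the 27 spike-in probe sets (open squares) on each array, by condition, with 1 array per point and 1 colour per strain. The S. pombe medians lie near 9 on both 43C arrays and near 10 on the other 6, while the spike-in means span 0.217 log2.

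Heat shock at 43C raised transcripts of chaperone and core stress genes in both strains. The largest rise was that of pcm2 (SPAC869.08), an isoaspartate methyltransferase that repairs damaged proteins, at 5.52 ± 0.24 log2 (SE, 2 arrays per condition), or 46 fold (adjusted p = 1.2e-05). It was followed by atf21, a bZIP transcription factor, at 5.41 ± 0.18, by mug150 at 5.27 ± 0.20, by ssa1, an HSP70 chaperone, at 5.07 ± 0.22, and by pyp2, a phosphatase of the stress kinase Sty1, at 4.64 ± 0.15. The genes mug106, mug153 and nab3 rose by 4.51, 4.50 and 4.03. The largest fall was that of fip1 (SPAC1F7.07C), an iron permease, at -4.31 ± 0.40 (adjusted p = 1.3e-04). It was followed by the histone deacetylase gene sir2 at -3.67 ± 0.08, rep2, an activator of G1/S transcription, at -3.36 ± 0.10, the serine synthesis gene ser2 at -3.28, the glutamine synthetase gene gln1 at -3.24, the iron transporter gene str3 at -2.81 ± 0.71, aes1 at -2.77 and meu18 at -2.65.

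Of 2892 genes, 950 rose and 1152 fell at 43C, 353 and 349 of them by at least 2-fold. On the deposited scale 323 rose and 2132 fell, so that 13.2% of called genes were higher in place of 45.2%, since the median over genes shifted down. The call for str3 was lost without the opi10- array before heat (adjusted p = 0.0641) or at 43C (0.0616). Against all 6 arrays at 30C, which include recovery, 513 rose and 631 fell, and pcm2, mug150, ssa1, nab3 and str3 were no longer called (adjusted p from 0.059 to 0.285).

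**Figure D2:**
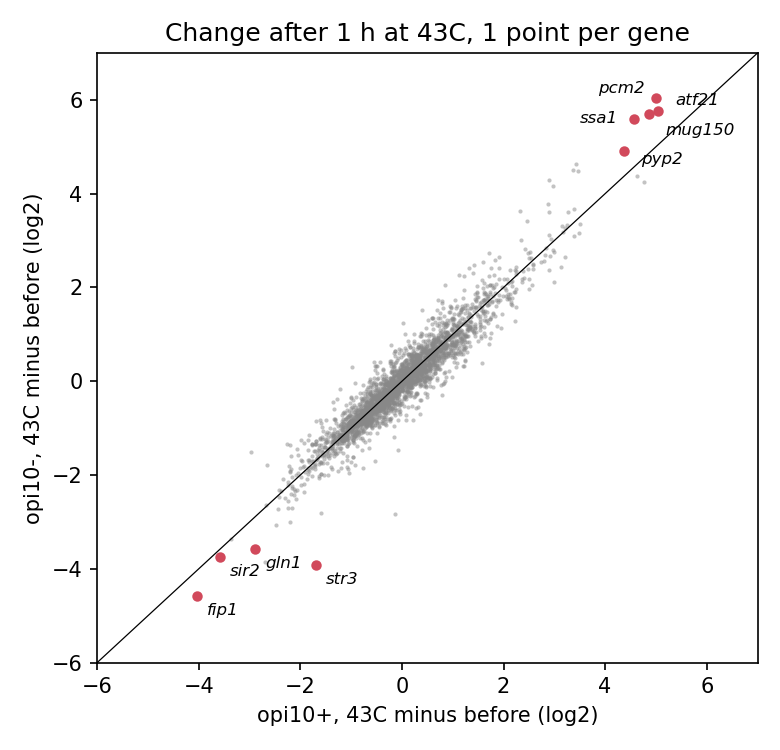
Change from before heat to 1 h at 43C in opi10+ (horizontal axis) and opi10- (vertical axis), in log2 after quantile normalization, with 1 grey point per tested gene, named genes in red and the line of equal change. Points follow the line, with pcm2 at 5.00 and 6.05 and fip1 at -4.04 and -4.58.

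Among 22 measured chaperone genes, 16 rose and 1 fell at 43C, or 15 and 1 of 21 without the misplaced ssp1, with a median of 1.08 log2 above all of the random lists. Beside ssa1, the Hsp40 gene psi1 rose by 3.24, the Hsp90 co-chaperone gene cdc37 by 1.99 and the mitochondrial Hsp40 gene mdj1 by 1.96, and bag102 fell by 1.35. In the HSP70 family, bip1 of the endoplasmic reticulum rose by 1.25 ± 0.23, the HSP110 gene pss1 by 1.12 ± 0.18 and mitochondrial ssc1 by 0.34 ± 0.09. The call of ssc1 was lost on the deposited scale (adjusted p = 0.0571) and without the opi10- array at 43C (0.0826), and those of ssc1 and pss1 against all arrays at 30C (0.0911 and 0.0658). The constitutive genes ssa2, at 0.23, and sks2, at -0.19, were not called, with adjusted p of 0.071 and 0.07, though sks2 fell by 0.54 on the deposited scale, where ssa2 was at -0.04. Of 34 core stress genes 19 rose and 6 fell, including rises of gld1 by 3.97, the sulfiredoxin gene srx1 by 1.80 and the trehalase gene ntp1 by 1.70. Counts adjusted over the list alone were 16 and 1 for chaperones and 19 and 6 for core stress, and on the deposited scale 13 and 4 chaperone genes and 16 and 10 core stress genes rose and fell.

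Genes of respiration and septation fell as groups at 43C. Of 42 respiratory chain and ATP synthase genes 31 fell and 2 rose, with a median of -0.48. The gene cox24 fell by 2.20, tim18 by 1.73 and atp20 by 1.47, while the assembly factor gene atp11 rose by 2.48. Of 27 mitosis and septation genes 16 fell and 4 rose, with a median of -0.56, including the septum glucanase gene eng1 at -2.47, adg1 at -1.75, etd1 at -1.53 and cdc15 at -1.52. The calls of eng1, adg1 and etd1 were lost against all arrays at 30C (adjusted p from 0.0536 to 0.321). Counts adjusted over the list alone were the same for both lists, and on the deposited scale 41 of 42 and 23 of 27 fell.

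Several lists depended on the scale. Of 119 ribosomal protein genes 76 fell and 2 rose at 43C with a median of -0.30 after quantile normalization, and adjusted over the list alone 75 fell and 2 rose, whereas on the deposited scale 111 fell and the median lay 0.28 above that of all genes, so their direction relative to other genes flipped. Of 19 autophagy genes 10 rose and 2 fell, of 10 histone genes 7 and 1, of 46 ribosome biogenesis genes 20 and 9, and of 91 mug genes, named for their induction in meiosis, 43 and 23, while on the deposited scale 3 and 11, 4 and 2, 2 and 24, and 25 and 45 did. Relative to all genes the medians of these 4 lists stayed positive on the deposited scale, at 0.47, 1.11, 0.50 and 0.54. Adjusted over the list alone the counts were 10 and 2, 7 and 1, 19 and 9, and 43 and 23. Examples were atg101 at 2.09, the histone variant gene pht1 at 1.26, the ribosome assembly gene bms1 at 1.83 and mug108 at 3.60, the last not called against all arrays at 30C (adjusted p = 0.0579). Of 42 nuclear transport genes 16 rose and 15 fell, also adjusted over the list alone, with the exportin gene crm1 at 1.92, kap114 at 1.54 and mex67 at 1.52 against the nucleoporin gene npp106 at -1.68. On the deposited scale 3 rose and 31 fell.

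**Figure D3:**
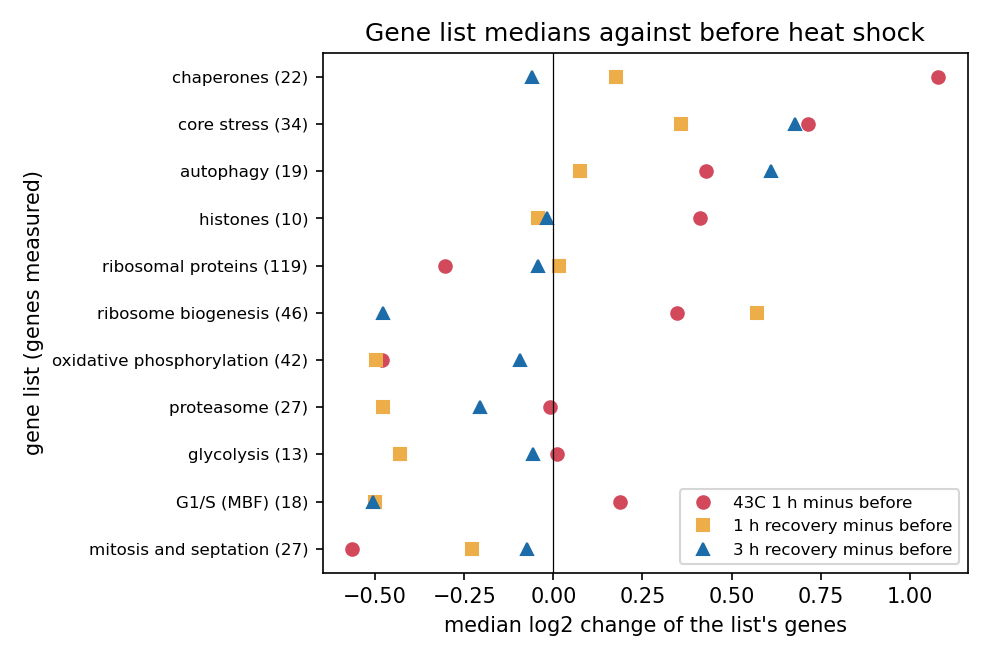
Median log2 change of 11 gene lists, as fixed before the data were examined, against before heat, at 43C (circles), 1 h of recovery (squares) and 3 h of recovery (triangles), with the number of measured genes in brackets. Chaperones lie at 1.08 at 43C and -0.06 at 3 h, and ribosome biogenesis at 0.57 at 1 h and -0.48 at 3 h of recovery; the ribosomal protein median at 43C, -0.30, turns positive relative to all genes on the deposited scale, at 0.28.

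After 1 h of recovery, most ribosome assembly genes were above their level before heat, and most respiratory and proteasome genes were below it. The largest rises were those of mug150 at 4.36 ± 0.20, ssa1 at 4.14 ± 0.22 (adjusted p = 4.4e-04), nab3 at 3.47 ± 0.30, the cation ATPase gene cta3 at 3.39 ± 0.33, pcm2 at 3.37, the galactosidase gene mel1 at 3.03, atf21 at 3.00 and pyp2 at 2.41. The largest falls were those of the iron genes str3 at -2.87 ± 0.71, fip1 at -2.75 ± 0.40, str1 at -2.32 and fio1 at -2.25, the invertase gene inv1 at -2.67 ± 0.50, eng1 at -2.52, the galactokinase gene gal1 at -2.09 and mug182 at -2.08. Of the HSP70 family only ssa1 and pss1, at 0.76, were called.

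In total 741 genes rose and 789 fell at 1 h of recovery, 100 and 103 by at least 2-fold. Leaving out the opi10- array at 1 h gave 396 and 448, and leaving out the opi10+ array 417 and 485. Without the opi10+ array inv1 and pss1 were no longer called (adjusted p = 0.0537 and 0.0988), without the opi10- array str1 was not (0.0641), and str3 was lost without either of them or without the opi10- array before heat (0.0533 to 0.12).

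Of 46 ribosome biogenesis genes 32 rose and 1 fell at 1 h of recovery, with a median of 0.57 above all random lists, or 29 and 1 of 43 without the misplaced genes. The gene bms1 rose by 1.16, dbp10 by 1.16, rlp24 by 1.08 and dbp2 by 1.07. Of 27 proteasome genes 20 fell and 1 rose, with a median of -0.48, including pts1 at -1.04 and pup1 at -0.94. Of 42 respiratory genes 30 fell and 3 rose, with cox8 at -1.34 and atp18 at -1.24. Of 13 glycolysis genes 9 fell and 1 rose, including the hexokinase genes hxk1 at -1.79 and hxk2 at -1.28, while the alcohol dehydrogenase gene adh4 rose by 0.83. Of 18 genes listed for G1/S transcription by the factor MBF, which include the activator gene rep2, 13 fell and 2 rose. The falls were led by rep2 at -1.87, cdt1 at -1.42, and cdc18 and mik1 at -1.15. Adjusted over the list alone the counts of rises and falls were 32 and 1, 1 and 20, 3 and 32, 1 and 9, and 2 and 13, in the same order of lists. Of 39 mitochondrial ribosomal protein genes 23 fell and 2 rose, 23 and 3 adjusted over the list alone, and 15 and 2 on the deposited scale.

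Core stress genes were raised in part at 1 h, with 12 rises and 4 falls among 34, or 8 and 4 adjusted over the list alone, and a median of 0.36. This median averages the strains. The change was higher in opi10- for 28 of the 34 genes, by a median of 0.48, which was not tested. Before heat the list stood at -0.39 in opi10- relative to opi10+. Of the 12, psk1, at 0.42, had fallen at 43C and atd3, at 0.82, had not been called there, both chosen after their values were seen. The largest were pyp2 and, in the other direction, the glutathione transferase gene gst2 at -1.54. Among 22 chaperone genes 6 rose and 2 fell, also adjusted over the list alone, including hsp16 at 1.77, psi1 at 1.62 and bag102 at -0.89. Of 16 iron genes 6 fell and 4 rose, or 8 and 4 adjusted over the list alone. The ferric reductase gene frp1 was at -2.38 but not called (adjusted p = 0.06).

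After 3 h of recovery, most core stress and autophagy genes stood above their level before heat, and most ribosome assembly genes stood below it. The gene mel1 rose by 4.33 ± 0.44 (adjusted p = 0.0022), ssa1 by 3.38 ± 0.22, pcm2 by 3.27, mug150 by 3.13, the hexose transporter genes ght1 by 3.07 ± 0.28 and ght4 by 2.77 ± 0.09, mug108 by 2.65 and cta3 by 2.32. The largest falls were those of mug94 at -1.81 ± 0.19, eng1 at -1.59 ± 0.41, ser2 at -1.54, meu18 at -1.52, the ribosome assembly helicase gene dbp3 at -1.48, gnr1, which encodes a G protein beta subunit, at -1.44, the RNA polymerase I subunit gene rpa34 at -1.43 and hut1 at -1.42. Of the HSP70 family only ssa1 was called, and the other members, ssp1 aside, lay between -0.20 and 0.00.

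At 3 h 569 genes rose and 643 fell, 85 and 40 by at least 2-fold, and on the deposited scale 776 rose and 330 fell, 70.2% in place of 46.9% higher. Leaving out the opi10- array before heat gave 291 and 292, leaving out the opi10- array at 3 h 275 and 318, and leaving out the opi10+ array at 3 h 379 and 426. The calls of eng1 and gnr1 were lost without the before array of either strain (adjusted p = 0.0702 and 0.0908 for eng1, 0.0664 and 0.107 for gnr1), and that of gnr1 also without the opi10+ array at 3 h (0.146).

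Of 34 core stress genes 21 rose and 3 fell at 3 h, with a median of 0.68, including gld1 at 2.21, the glycerol-3-phosphate dehydrogenase gene gut2 at 1.72 and pyp2 at 1.71. Of 19 autophagy genes 14 rose and none fell, with a median of 0.61, including atg101 at 1.37, atg6 at 0.93, atg4 at 0.92 and atg1801 at 0.91. Of 46 ribosome biogenesis genes 28 fell and 2 rose, or 28 and 0 of 43 without the misplaced genes, including ebp2 at -1.24 and utp23 at -1.06. Of 18 G1/S genes 8 fell and none rose, led by rep2 at -1.35 and cdt1 at -1.01, the latter not called without the opi10- array before heat (adjusted p = 0.0641) or the opi10+ array at 3 h (0.0761). Of 42 nuclear transport genes 15 fell and 2 rose, including pim1, the Ran exchange factor gene, at -0.93. Of 18 mating genes 9 rose and 3 fell, with spk1 at 1.40 and ste11 at 1.19. Adjusted over the list alone the rises and falls were 22 and 3, 15 and 0, 2 and 28, 0 and 8, 2 and 15, and 9 and 4, in the same order. On the deposited scale they were 22 and 2, 16 and 0, 3 and 19, 0 and 3, 3 and 11, and 11 and 1, and none of the medians changed direction relative to all genes. All of these changes average the strains. The median response in opi10- minus that in opi10+ was 0.39, 0.43, -0.43, 0.21, -0.10 and 0.06, in the same order, and was not tested.

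Over all 4 conditions, limma called no gene as different between opi10- and opi10+, the smallest adjusted p being 0.296. At an unadjusted p under 0.05 there were 317 genes, against 145 of 2892 expected by chance from independent arrays. The arrays of a strain may come from 1 culture and genes vary together, so this excess was not tested and shows no strain effect. Leaving out either array before heat gave 1 call, ima1, which was lower in opi10- by 1.08 log2 over the other conditions (adjusted p = 0.0117). No named gene differed by at least 2-fold the same way in all 4 conditions.

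Before heat, opi10- had lower levels of stress and autophagy genes than opi10+ and higher levels of ribosome assembly genes, in 1 array against 1. The lowest values in opi10- relative to opi10+ were those of inv1 at -2.08, with signals of 1540 and 6610, rds1 at -1.61, mug108 at -1.61 and gld1 at -1.38. The highest were those of str3 at 1.94, frp1 at 1.77, the telomeric helicase gene tlh2 at 1.31 and the meiotic cohesin gene rec8 at 0.85. The probe sets of tlh2 disagreed, with strain differences over all conditions of 0.608, 0.571, 0.186 and 0.0968. Of 34 core stress genes 28 were lower, with a median of -0.39, below all of the random lists, including ish1 at -1.22 and the metallothionein gene zym1 at -0.99. All 19 autophagy genes were lower, with a median of -0.31, and 38 of 46 ribosome biogenesis genes were higher, with a median of 0.14. The 16 iron genes had 8 higher and 8 lower, with a median of -0.04, although str3 and frp1 were high. In all 3 genes were at least 2-fold higher and 16 lower, against 4 of 2601 S. cerevisiae probe sets beyond 2-fold either way. On the deposited scale the counts were 3 and 27, and with a pseudocount of 1 the total was 39 genes. The S. cerevisiae probe sets, here and in the comparisons below, are dim, with a median signal of 2.46, and were not quantile normalized. Their counts show the spread near background and not that of genes at higher signals.

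At 43C the strains were close, with 2 genes at least 2-fold higher and 9 lower in opi10-, against 3 of 2601 S. cerevisiae probe sets, and 1 and 4 genes on the deposited scale. The total depended on the pseudocount, with 30 genes at a pseudocount of 1 and 3 at 64. The kinase gene ppk31 was higher by 1.19, fta6 by 1.16, vrs2 by 0.99 and SPAC16E8.05C by 0.92, and gnr1 was at -1.40, mug93 at -1.29, the pheromone gene mfm3 at -1.26 and mug130 at -1.23. Apart from ppk31, with signals of 364 and 1090, and gnr1, with 132 and 53.5, these genes had signals under 100 on both arrays. Of 119 ribosomal protein genes 112 were higher, with a median of 0.09, and 59 of 91 mug genes were lower, with a median of -0.14.

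At 1 h of recovery the median of the chaperone genes was lower in opi10-, at -0.24 below all of the random lists and values below 0 for 14 of 22 genes, or -0.30 for 21 genes without the misplaced ssp1. The Hsp90 co-chaperone gene sti1 was at -0.75, mdj1 at -0.59, ssa1 at -0.54 and the Hsp40 gene mas5 at -0.50. Before heat, where the chaperone median was 0.06, ssa1 had been at -1.09 and hsp16 at -1.04, so that the change of ssa1 up to 1 h of recovery was 4.41 in opi10- and 3.87 in opi10+. Respiratory genes were higher in 35 of 42 cases, with a median of 0.10. The highest single genes were ppk31 at 1.57, mel1 at 1.23, gst2 at 0.86 and nhp6 at 0.70, and the lowest were mde6 at -1.41, ima1 at -1.04, mug35 at -0.94 and sap1 at -0.92. Only 2 genes in each direction were beyond 2-fold, against 5 of 2601 S. cerevisiae probe sets, and 10 genes in total were with a pseudocount of 1.

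At 3 h of recovery, iron uptake, septation and G1/S genes were higher in opi10- and ribosome assembly genes lower. The ferric reductase gene frp1 was higher by 3.19, with signals of 1280 and 162, str3 by 3.09, the metal transporter gene fet4 by 1.99, fip1 by 1.88 and fio1 by 1.69. Of 16 iron genes 13 were higher, with a median of 0.29. Of 27 mitosis and septation genes 22 were higher, with a median of 0.18, including adg1, eng1, adg2 and adg3 at 1.60, 1.57, 1.53 and 0.94. Of 18 G1/S genes 15 were higher, with a median of 0.33, including the ribonucleotide reductase gene cdc22 at 1.39 and cdt2 at 0.97. Of 46 ribosome biogenesis genes 42 were lower, with a median of -0.24, including dbp3 at -0.85, and the lowest single genes were nab3 at -1.14, ima1 at -1.12, the RNA polymerase I factor gene rrn3 at -1.07 and mug93 at -0.97. In the HSP70 family bip1 was at -0.86, ssa1 at -0.38 and pss1 at -0.31. In all 13 genes were at least 2-fold higher and 3 lower, against 9 of 2601 S. cerevisiae probe sets, and 10 and 5 on the deposited scale. A pseudocount of 1 gave a total of 27 genes.

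**Figure D4:**
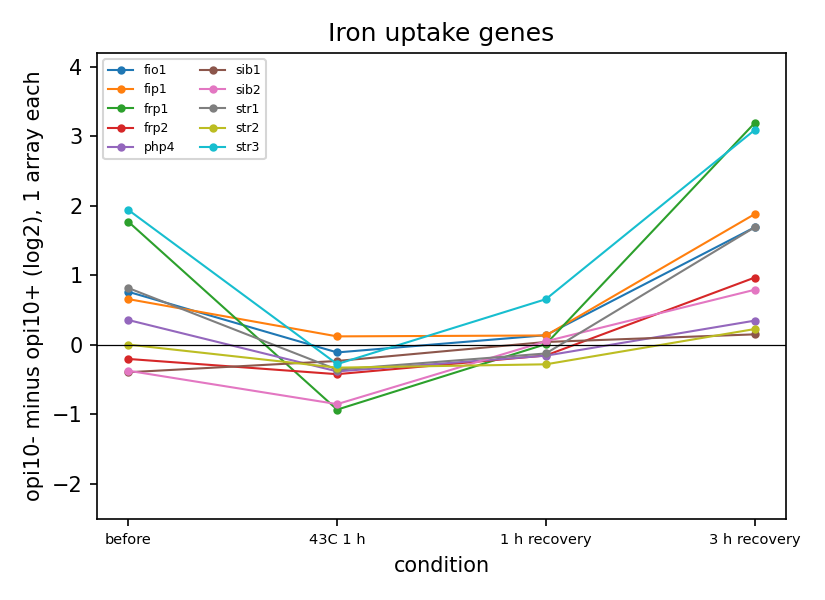
Level in opi10- minus opi10+ in log2 at each condition, 1 array against 1, for 10 iron uptake genes, each line being a gene; the set was put together after the differences had been seen. At 3 h of recovery frp1 stands at 3.19 and str3 at 3.09.

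The responses of the strains were compared directly as the change in opi10- minus the change in opi10+. Across genes the changes at 43C in the 2 strains had a Pearson r of 0.949 and a total least squares slope of 1.03, those at 1 h of recovery an r of 0.873 and a slope of 1.10, and those at 3 h an r of 0.839 and a slope of 1.42. The response differed by at least 2-fold for 32, 27 and 37 genes, while 38, 52 and 51 of 2601 S. cerevisiae probe sets, which are dim, differed by as much. These gene counts were 67, 46 and 57 with a pseudocount of 1. They were 12 and 17 at 43C and 1 h with a pseudocount of 64, and 71 at 43C with spike-in centring. At 43C inv1 was at -2.97 in opi10+ and -1.51 in opi10-, frp1 was at -0.14 and -2.84, and ppk31 at 2.33 and 3.63. At 1 h of recovery mel1 was at 1.97 in opi10+ and 4.10 in opi10-, tcb2 at -0.25 and 1.58, and rds1 at -0.19 and 1.55. At 3 h inv1 was at 0.06 and 2.38, fet4 at 0.21 and 2.01, adg1 at -1.74 and -0.11, dbp3 at -0.92 and -2.04, and bip1 at 0.39 and -0.63. By list, the median response of core stress genes was higher in opi10- by 0.21, 0.48 and 0.39 at 43C, 1 h and 3 h, and that of autophagy genes by 0.30, 0.32 and 0.43, all above all of the random lists. That of ribosome biogenesis genes was at -0.07, -0.19 and -0.43. Each of these differences includes the arrays before heat, where these 3 lists, inv1, rds1, mug108, frp1 and str3 already differed, and none was tested.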

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

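All tests in this part, and the bounds they were held to, were chosen after the results were seen.

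Unnamed probe sets, which the comparisons did not use, held signals above the S. cerevisiae background, and 2 of these sets differed by at least 2-fold between the strains in the same direction in all 4 conditions. On the deposited scale the difference between the strains before heat (opi10- minus opi10+) was -4.97 log2 for 1772771_at and -2.03 for 1779357_at, the latter with signals of 78.9 and 373. The signal of 1772771_at in opi10- was at background in all 4 conditions, so its differences are limited by the pseudocount of 16 and are bounds, the level being lower by at least this much. Over the 4 conditions 1779357_at lay between -1.30 and -2.33. When unnamed probe sets above the stricter filter were tested too, 1772771_at was the only strain call among 5126, at a bound of -5.17 after quantile normalization (adjusted p = 0.00736). A total of 2234 unnamed probe sets had a mean above the stricter background level. Among these, 695 rose and 753 fell at 43C, so that a large part of the response carries no gene name here.

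No named gene was called between the strains over all conditions. Of the 35 splits of the 8 arrays into 4 and 4, 32 could be fitted beside the condition term. The real split gave 0 calls and the highest of the others gave 0. Since every split gives at least 0 calls, the count of 32 of 32 splits with as many was fixed in advance and decides nothing.

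The median signal of S. pombe probe sets was lower on both 43C arrays. The spike-in probe sets moved by a mean of only 0.0072 log2, which argues against dimmer hybridization or scanning, although spike-ins say nothing about steps before they were added. The 3' to 5' signal ratios of 4 control mRNAs moved by a mean of -0.055 log2, 2 of them lying above and 2 below the range of the 30C arrays on both 43C arrays. The changes were 0.328 for act1 and 0.356 for SPCC338.15, against -0.353 for rip1 and -0.551 for tfiid. Not all ratios rose, but with this even split the ratios cannot decide whether RNA was degraded. The signal gained by rising probe sets was 21.4% of that lost by the others, but 16 probe sets stood at 10000 or more on both 43C arrays, near the top of the scale, so a few bright genes taking the signal cannot be told apart from a lower share of the other transcripts. A fall in mRNA per amount of RNA after heat shock stays open and was not tested.

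The iron uptake genes of the Fep1 regulon, a list of 10 measured genes written after some of them had been seen, were higher in opi10- at 3 h of recovery, with a median of 1.33 log2, after 0.51 before heat, -0.34 at 43C and 0.03 at 1 h. On the deposited scale the median relative to all genes was 1.19. A common shift between arrays cancels in this value, so it shows only that quantile normalization did not produce the difference. The iron list fixed beforehand, with 16 measured genes, had a smaller median of 0.29. All 10 genes lay above the stricter background level on both arrays, which argues against noise near background. Iron-using genes, which fall in iron-starved cells, had a median of 0.0641, within 2 SDs of random lists, so iron shortage in the opi10- culture cannot be told apart from another cause. The opi10 genotype and the state of this 1 culture are the same contrast in this design, and the genotype was not tested.

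Stress and autophagy genes were lower in opi10- before heat, the core stress list by a median of -0.39. Relative to all genes on the deposited scale the median was -0.459. A common shift between arrays cancels in this value too, so it shows only that quantile normalization did not produce the difference. The later medians were -0.0583 at 43C, -0.0458 at 1 h and 0.0415 at 3 h (-0.145, -0.0417 and 0.0595 relative to all genes as deposited), which argues against a difference of this size in every condition but leaves a smaller one of the same sign at 43C and 1 h. Ribosome biogenesis genes, with a median of 0.144, and ribosomal protein genes, with 0.0519, were higher in opi10- than in random lists. The hypothesis of an opi10+ culture nearer the end of growth requires this. The rise was seen on the same arrays before the bound was set, however, so it does not single out that hypothesis. With 1 culture per group an effect of opi10 limited to growth before heat stays open and was not tested.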

How the results depend on the processing

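Centring on spike-ins, testing unnamed probe sets and comparing list medians relative to all genes were chosen after the data were seen. Of 166 tested values of named genes 151 were called. Of these, 125 stayed called in every alternative, 26 lost the call in at least 1 (14 when an array was left out, 17 in others) and 0 reversed. Most of these genes were named for the size of their change, so the numbers do not describe the calls of other genes. Leaving out 1 array, where the lone array of a condition is assumed to vary like the others, gave 808 to 964 rises and 996 to 1142 falls at 43C, 396 to 727 and 448 to 787 at 1 h, 275 to 568 and 292 to 625 at 3 h, and 0 to 1 strain calls. Pairing by replicate number was not possible because the groups share only 1 replicate number. The main model already pairs arrays by strain and by condition, and leaving out either term moved no count of calls by over 1.5 times. The causes of the changes below were not tested, except that more probe sets give more calls and a common shift between arrays moves calls in its direction. As deposited, 323 genes rose and 2132 fell at 43C and 330 fell at 3 h. With spike-in centring 296 rose and 2091 fell at 43C, and 403 fell at 1 h and 147 at 3 h. With unnamed probe sets 1602 rose and 1941 fell at 43C, 1230 and 1298 at 1 h, 984 and 1150 at 3 h, and 1 was called between strains. Against all 30C arrays 513 rose and 631 fell at 43C. Strain differences beyond 2-fold numbered 39 before heat, 30 at 43C, 10 at 1 h and 27 at 3 h with a pseudocount of 1, 3 at 43C with 64, 30 before heat and 5 at 43C as deposited, and 6 at 43C with median or spike-in centring. Response differences beyond 2-fold numbered 67, 46 and 57 with a pseudocount of 1, 12 and 17 at 43C and 1 h with 64, and 71 at 43C with spike-in centring. Of the list medians outside the range of random lists, 3 reversed relative to all genes, as deposited or centred on the median or on spike-ins: ribosomal proteins at 43C (0.2789), ribosomal proteins between strains at 3 h (0.005856), and amino acid synthesis at 3 h (-0.04527). Another 22 of the 175 medians, all within that range, changed sign as deposited. Plain medians as deposited, which include the shift of all genes, turned at 43C for 8 of 25 lists: autophagy (-0.447), mug genes (-0.372), ribosome biogenesis (-0.414), nuclear transport (-0.836), G1/S (-0.777), nitrogen starvation (-0.392), ubiquitin (-0.533) and glycolysis (-0.134), and for 1 to 10 lists in each other comparison. The stricter filter would remove few genes, since 2885 of 2892 lay above it. It uses means over the 8 arrays, so passing it does not show that low signal left the strain differences unaffected. The number beyond 2-fold at 43C was 11 in the main setting, against 30 with a pseudocount of 1 and 3 with 64.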

Other observations

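The gene sets and hypotheses in this part were chosen after the results were seen.

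Hexose transporter and sugar use genes, a list of 14 measured genes, changed at several stages. At 43C 9 of them rose and 3 fell, with a median of 0.65 log2, and at 1 h of recovery 4 rose and 7 fell. On the deposited scale 5 rose and 5 fell at 43C, with a median of -0.07, or 0.84 relative to all genes. At 3 h 8 rose and none fell, with a median of 0.80, led by mel1 at 4.33, ght1 at 3.07 and ght4 at 2.77. In 1 array against 1, the list was lower in opi10- than in opi10+ before heat, with a median of -0.36 and 10 of 14 genes lower, and higher at 3 h, with a median of 0.38 and 10 of 14 genes higher. The invertase gene inv1 had a signal of 6610 before heat and 6550 at 3 h in opi10+, and of 1540 and 7600 in opi10-.

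The 353 genes that rose by at least 2-fold at 43C had a lower median in opi10- than in opi10+ in each condition, by 0.10 log2 before heat, 0.07 at 43C, 0.12 at 1 h and 0.05 at 3 h of recovery. The 349 genes that fell as much had a higher one, by 0.07, 0.04, 0.09 and 0.09. On the deposited scale the value before heat was -0.01, or 0.06 relative to all genes. These are differences between single arrays, and the sets were defined from the same arrays.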
